A study of Mus musculus with 7 samples.

How the data were processed

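Total RNA was isolated from frozen whole kidneys of male mice 3.5 to 4 weeks old, and 100 ng per sample was labelled with Cy3, per the labels' protocols. Each sample was read on 1 Agilent mouse microRNA array. Spot intensity values were extracted by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The deposited scanner intensity columns hold background-subtracted signals, raw medians of spot and local background, and the software's total signal per microRNA, with no scaling between arrays. The authors' deposited value table also holds intensity values. All of its values are whole numbers from 20 to 9741, each column's median is 20 and each column's maximum is 9741. Its scaling method is not given in the sources used here, and its columns correlated with the total gene signal of their own array at 0.990 to 0.996 (Pearson, across tested microRNAs before the break described next, log2 scale).

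That table has 717 rows, all matched to a probe, for 650 microRNA names. In alphabetical order, all 240 names above the table's floor among the first 527 lay within 1 log2 unit of their own total gene signal, after bringing arrays to one distribution. Among the last 123 names, all 38 above the floor lay within 1 log2 unit of the signal of the name just before, and 19 within 1 unit of their own. The table served as an alternative only, for the 190 tested microRNAs before that break.

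Control spots and spots flagged as outliers (3.45% to 3.77% per array) were left out, and no spot was saturated. Signals were averaged over the spots of a probe and scaled by the array's 75th percentile over the 292 probes detected on all 7 arrays, because under 22% of probes were detected. Scaled signals were floored at 11.4 units, the median over arrays of the 1st percentile among probes well above background, and put on a log2 scale. The level of a microRNA is the mean over its probes well above background on at least 3 arrays, and a probe counted as such where at least 0.5 of its spots were. Viral microRNAs on the array were not tested. The number of arrays limits the precision.

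Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 over 213 microRNAs. Differences are megabladder minus wild-type. Before the data were examined, 14 microRNA lists, the alternatives and the rule for named microRNAs were fixed. Lists with at least 3 tested members (10 of 14) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The lists of smooth muscle, Dlk1-Dio3, other tissue and near-Myocd microRNAs had too few for that. The rule named microRNAs past the threshold with no overlap between groups, up to 15 rises and 10 falls, filled up to 10 by smallest p, up to 3 of each list by smallest p, and miR-744, miR-205, miR-21 and miR-192. Other names in the text were chosen after their values were seen.

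The fit was tested on simulated data made from the real means and spreads of the 213 microRNAs, each drawn independently and with no floor. In 20 runs with no change, the mean number of calls was 0, and a shift of 0.5 log2 units in the 12 tubule microRNAs was called by camera in 20 of 20 runs. With no change, camera called a mean of 0.05 lists, while 32 of 35 splits of the real arrays gave at least 1. Correlation between microRNAs was not simulated, so these rates do not carry over where microRNAs move together. Names of tested microRNAs were looked up in the RefSeq annotation of GRCm38.p6, and 186 of 213 matched. The files name another mouse build, so no coordinates are given. Alternatives covered the scaling, signal, background, filter, probes, floor, test, block and single arrays. Normexp (offset 50) used the median spot signal in place of the mean spot signal that had been planned. Figures were drawn with matplotlib from these values.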

Results

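The megabladder mouse is a mutant line whose bladder develops without normal smooth muscle, so that urine outflow is obstructed and the kidneys dilate after birth. MicroRNAs were measured in whole kidneys of young males on 1-colour Agilent arrays, in 4 wild-type mice and 3 homozygous megabladder mice, 1 array per mouse. The series text names 4 mutant kidneys, and megabladder mouse 1 was not analysed here. The comparison between the genotypes asks which kidney microRNAs differ at 3.5 to 4 weeks of age in this model of obstructive kidney disease. Labels name each array for a separate mouse. As a check for one array deposited more than once, the median absolute difference was at least 2.13 standard errors between spots in every pair, where spot noise alone gives 0.674. That comparison does not bear on whether the mice were separate.

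Each array found 190 to 210 of 611 mouse microRNAs above background, and 19.0% to 21.8% of its 1857 probes. The 7 arrays shared 1 slide and 1 scan. All wild-type arrays lay in 1 slide row and all megabladder arrays in the other, so slide row and genotype cannot be told apart. The 75th percentile of probes detected on all arrays was 348.1 to 495.8 units in wild-type and 223.5 to 333.4 units in megabladder arrays. On the log2 scale the scaling factors were 0.61 lower in megabladder arrays, and the genotypes did not overlap (2-sided exact permutation p = 0.0286, the smallest that 35 splits allow). Arrays of microRNAs do not measure Myocd messenger RNA, the transcript of the smooth muscle regulator disturbed in this line, and so cannot check the mutation. The microRNA miR-744, which lies within Map2k4 next to Myocd in the GRCm38.p6 annotation, was not well above background on any array with any of its 4 probes.

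In megabladder kidneys 6 microRNAs rose and 1 fell among 213 tested. The risen ones were miR-715 (2.19-fold), let-7b* (1.79-fold), miR-1894-5p (1.71-fold), let-7d* (1.69-fold), miR-328 (1.59-fold) and miR-297a* (1.52-fold). let-7b* and let-7d* are the passenger arms of let-7 precursors, the strands that are usually degraded. let-7e, a guide strand of the let-7 family, which restrains growth and stem cell programmes, was 1.49-fold lower. All 7 had an adjusted p of 0.0315 in limma, and in each the 3 megabladder values lay on one side of the 4 wild-type values.

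The level of miR-715 was 3.83 ± 0.36 log2 units (SD, n = 4) in wild-type and 4.96 ± 0.09 (SD, n = 3) in megabladder kidneys, a difference of 1.13 with a 95% interval of 0.67 to 1.60. let-7e stood at 8.25 ± 0.06 in wild-type and 7.68 ± 0.12 in megabladder kidneys, a difference of -0.57 (interval -0.79 to -0.36). The 6 risen microRNAs were dim, with mean levels of 14.3 to 19.9 scanner units against a floor of 11.4 units. Wild-type values of let-7d*, miR-1894-5p and miR-297a* were at the floor on 2 arrays and that of let-7b* on 1 array, so their folds are measured in part against the floor. Among all 213 microRNAs, 49 had an unadjusted p under 0.05, of which 43 were higher and 6 lower in megabladder kidneys. In the main scaling the groups did not overlap for 22.1% of microRNAs, where chance gives 5.71% for a single microRNA. All 213 share the same arrays, whose scaling factors did not overlap between genotypes, so the excess is no test of many changes. In simulations of the 213 microRNAs, drawn independently and with no floor, 20 were changed by each of 0.5, 1 and 2 log2 units. Of the changed ones, 56.5%, 86.0% and 95% were called, and of the unchanged ones 1.47%. With so many changed at once the adjusted threshold is easier to pass, so these rates do not give the power in the real data.

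**Figure D1:**
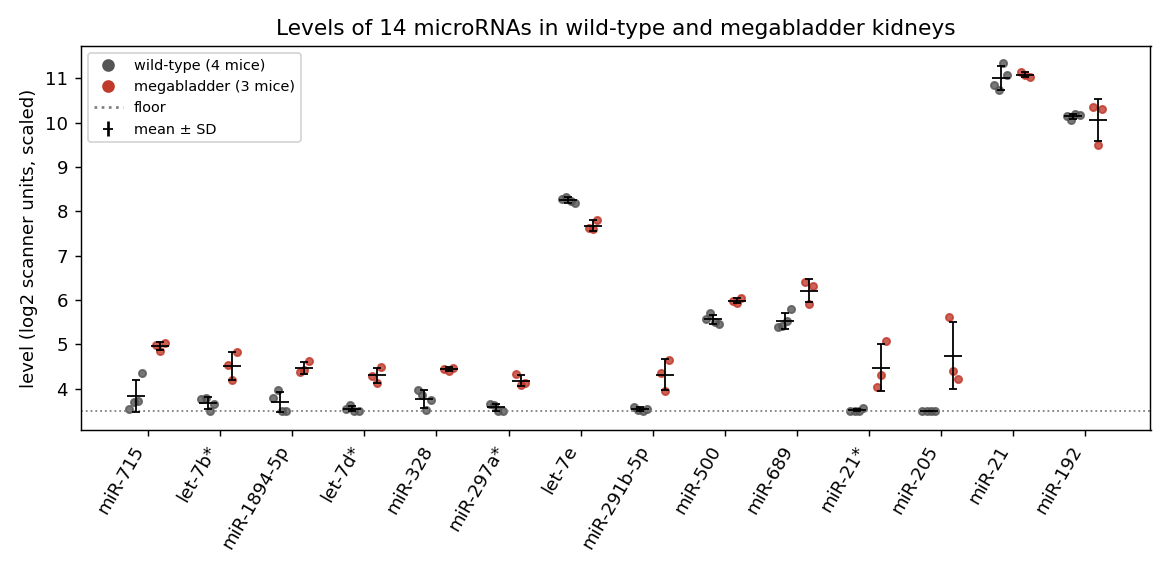
Level of 14 microRNAs on each array, in log2 scaled scanner units. Points are mice, bars are mean ± SD and the dotted line is the floor. The 3 megabladder values of the 6 risen microRNAs lie above all wild-type values, those of let-7e lie below them, and all 4 wild-type values of miR-205 lie on the floor.

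The count depended on how arrays were scaled. Against 6 higher and 1 lower in the main scaling, scaling by all probes or by quantiles gave 0 calls, scaling by the median gave 0 higher and 1 lower, and leaving signals unscaled gave 1 higher and 68 lower. Limma's unadjusted p was under 0.05 for 107 microRNAs with scaling by all probes and for 40 with quantiles. These scalings moved the median log2 fold change of all microRNAs from 0.09 to -0.62 (all probes), -0.10 (quantiles), -0.15 (median) and -0.50 (unscaled). All scalings but quantiles use 1 factor per array and so move every log2 fold change alike, apart from the floor. Values relative to the median of all microRNAs therefore agree between those scalings largely by construction. Relative to that median, let-7e was lower by all 5 scalings, at -0.69 to -0.51, and miR-715 was higher by all 5, at 0.61 to 1.05. So were let-7b* (0.48 to 0.79), let-7d* (0.48 to 0.92), miR-1894-5p (0.54 to 1.02) and miR-297a* (0.40 to 0.86). Their own log2 fold changes shrank, to 0.15 for let-7b* and 0.29 for let-7d* with all probes, and to 0.33 for miR-1894-5p and 0.18 for miR-297a* unscaled, and that of miR-715 to 0.38 with all probes. let-7e had -1.31 with all probes. miR-328 was 0.15 to 0.58 above the median, and its own log2 fold change turned to -0.07 with scaling by all probes. In the authors' deposited values let-7b* had 0.29, let-7d* 0.06, miR-297a* 0.24, miR-328 0.04 and miR-1894-5p 0.67, and let-7e was the 1 microRNA called. With normexp the 6 higher ones had 0.41 to 0.55 and let-7e -0.37. Normexp also raised other microRNAs: the leukocyte list's median went from -0.15 to 0.32 and the endothelial list's from -0.06 to 0.30. Those of the tubule (-0.03), miR-200 (0.00) and miR-29 and let-7 (-0.26) lists did not rise. The medians of the fibrosis list (0.42), the urothelium list (0.405) and the p53 and hypoxia list (0.37) came near the values of the 6. The 6 rises with normexp are thus close in size to those of some uncalled microRNAs. With a floor of 1 miR-1894-5p had 2.30 and miR-297a* 2.22. Without wild-type mouse 1, 2 or 3 no microRNA passed in limma (44, 45 and 25 at an unadjusted p under 0.05). The count was 1 without wild-type mouse 4, 1 without megabladder mouse 2, 11 without megabladder mouse 3 and 4 without megabladder mouse 4. In an alternative chosen after seeing the data, leaving out wild-type mice 3 and 4 together gave 1.

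The microRNAs next in order of p did not pass. They were miR-291b-5p (log2 fold change 0.77, adjusted p = 0.0510), miR-500 (0.42, 0.0551) and miR-689 (0.68, 0.0551), each with all megabladder values above all wild-type values. Without megabladder mouse 3, miR-291b-5p (0.99, adjusted p = 0.0243) and miR-689 (0.84, 0.0421) passed. Over all alternatives their adjusted p ran from 0.00559 to 0.655 and from 0.00878 to 0.880. None of the 4 called microRNAs with several probes had probes that differed in sign. Among 163 tested microRNAs with several probes, 20 did.

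The list of microRNAs associated with fibrosis had 8 tested members, of which none passed singly over all microRNAs and 1 (miR-21*) passed when adjusted over the list alone. Their median log2 fold change was 0.38, and 0.23 without megabladder mouse 3. miR-21*, the passenger arm of miR-21, had 0.95 (adjusted p = 0.0551) with 3 of 4 wild-type arrays at the floor. It passed without megabladder mouse 4, at 0.93 (adjusted p = 0.0251, and 0.0251 to 0.386 over all alternatives). miR-199b* had 0.59 and miR-199a-5p 0.39, both from a family carried by stromal cells. miR-21 itself, an abundant microRNA raised in many fibrotic tissues, had 0.09 (95% interval -0.28 to 0.45), at 11.0 ± 0.27 in wild-type and 11.09 ± 0.05 in megabladder kidneys. Camera gave the list an adjusted p of 0.236 and fry, which asks whether members move one way without comparing them with others, gave 6.19e-04. The list's median was -0.29 with scaling by all probes and -0.16 unscaled, and 0.25 to 0.34 above the median of all microRNAs by the 5 scalings. Apart from the floor, only quantile scaling could alter that relative value.

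The list of miR-29 and let-7 microRNAs, held to restrain matrix genes, had 12 tested members. let-7e fell, 11 did not pass, and the count adjusted over the list alone was also 1. The log2 fold change was negative for 11 members, with let-7f at -0.30 and let-7a at -0.26, and positive for let-7i. Their median was -0.25, and -0.14 without megabladder mouse 3, and camera placed the list below other microRNAs (adjusted p = 2.42e-05). That call was lost with an estimated correlation, where the adjusted p was 0.483, and fry gave an adjusted p of 0.240. Scaling by all probes (adjusted p = 0.0922), scaling by quantiles (0.288), the authors' deposited values (0.488) and leaving out wild-type mice 3 and 4 (0.0854) ended it too, while the median stayed negative in each. The levels of miR-29a ran from 8.67 to 10.46 among the wild-type mice, the highest being mice 3 and 4 at 10.46 and 10.27, against 8.85 to 9.79 in megabladder mice.

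Kidney tubule microRNAs did not pass singly in any of 12 tested members, nor when adjusted over the list alone. miR-192, abundant in the proximal tubule, had -0.09 (95% interval -0.58 to 0.39), miR-204 had 0.50, miR-30d 0.26 and miR-30b -0.13. The list's median was -0.01, its mean 0.03 and camera placed it below other microRNAs, with an adjusted p of 0.242. The list passed in camera with normexp (adjusted p = 0.0140) and with no filter (0.0353), and its median was 0.07 without megabladder mouse 3. The 5 members of the miR-200 family, which maintains epithelial identity, ranged from -0.14 for miR-200a to 0.07. miR-200b had -0.12 and miR-429 0.06, and none passed (camera adjusted p = 0.236, placed below, with a median of 0.00 and a mean of -0.03). Without megabladder mouse 3 the median was -0.11 (adjusted p = 0.0523), and with no filter the list passed in camera (adjusted p = 0.00446).

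Among markers of other cell types, miR-205 of urothelium and stratified epithelium stood at 5.61, 4.41 and 4.21 in megabladder mice 2, 3 and 4 and at the floor on all 4 wild-type arrays, with a probe above background on 1 of them. Its log2 fold change of 1.23 (adjusted p = 0.0712; 0.65 to 1.23 over the 5 scalings) is therefore measured against the floor, and the fit holds no spread between its wild-type values. It did not pass over all microRNAs, and passed when adjusted over its list alone, as 1 of 5 tested members. It passed over all microRNAs without megabladder mouse 2, at 0.84 (adjusted p = 0.0487), and its adjusted p over all alternatives ran from 0.0145 to 0.509. miR-31 had 0.44, with 3 wild-type arrays and 1 megabladder array at the floor, and miR-203 had -0.17. Without megabladder mouse 4, miR-31 passed at 0.70 (adjusted p = 0.0251, and 0.0251 to 0.969 over all alternatives). Camera gave this list an adjusted p of 0.874, with a median of 0.11, which was 0.38 without megabladder mouse 4, 0.03 without megabladder mouse 2 and below 0 without megabladder mouse 3 (-0.00300) or wild-type mouse 1 (-0.00457).

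None of 5 leukocyte microRNAs passed, with miR-155 at -0.47, miR-342-3p at 0.28 and miR-146a at -0.15, a median of -0.15 and a camera adjusted p of 0.236. The 3 erythroid microRNAs had 0.32 for miR-486, 0.11 for miR-144 and 0.04 for miR-451. Their median was 0.11, while camera, which compares with other microRNAs, placed them below (adjusted p = 0.945). The median was -0.22 without megabladder mouse 4 and 0.47 without megabladder mouse 2. The 2 tested smooth muscle microRNAs, miR-145 (0.24) and miR-143 (0.09), did not pass. None of 7 endothelial microRNAs passed, with miR-126-5p at -0.23, miR-322 at 0.21, miR-503 at 0.24, a median of -0.06 and a camera adjusted p of 0.236. Without megabladder mouse 3 the leukocyte and endothelial medians were 0.06 and 0.09. The leukocyte list passed in camera with total gene signal (adjusted p = 0.00767) and the endothelial list with no filter (0.00821). miR-128 (0.11) and miR-7a (0.03), tested members of the list of neuron, liver and pancreas microRNAs, did not pass. These lists, like those of the tubule and the miR-200 family, had 0 members past the test when adjusted over the list alone.

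In the cell cycle associated miR-17-92 and related clusters 9 of 10 tested members had positive log2 fold changes and none passed. miR-18a had 0.27, miR-106b 0.21 and miR-92a 0.13, and camera gave an adjusted p of 0.945. The 4 p53 and hypoxia microRNAs included miR-34a at -0.45, miR-210 at 0.29 and miR-34b-5p at 0.09. Their median was 0.03 and their mean -0.02, and camera placed them below other microRNAs (adjusted p = 0.453). Without megabladder mouse 3 the median was -0.23 and the list passed in camera (adjusted p = 0.0140). The positive value of miR-210 rested on that mouse, at 5.82 against a wild-type mean of 4.38. Megabladder mice 2 and 4 lay below that mean, at 4.05 and 4.12. Of 45 microRNAs of the imprinted Dlk1-Dio3 cluster 1 was tested, miR-494 at 0.60, which did not pass (adjusted p = 0.471). None of these 3 lists had a member past the test when adjusted over the list alone. Because the other scalings lowered the median of all microRNAs, positive values could turn negative under them. Of 34 named microRNAs with a positive value, 25 turned negative under some scaling, while 0 of 12 with a negative value changed sign. Larger values turned too, with the lowest at -0.17 for miR-204, -0.14 for miR-494 and -0.155 for miR-199b*. Relative to that median, by the 5 scalings, miR-204 was at 0.35 to 0.45, miR-30d at 0.14 to 0.29 and miR-199a-5p at 0.28 to 0.37, while miR-145 (-0.16 to 0.15) and miR-18a (-0.10 to 0.18) changed sign. Apart from the floor, only quantile scaling could alter these relative values.

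**Figure D2:**
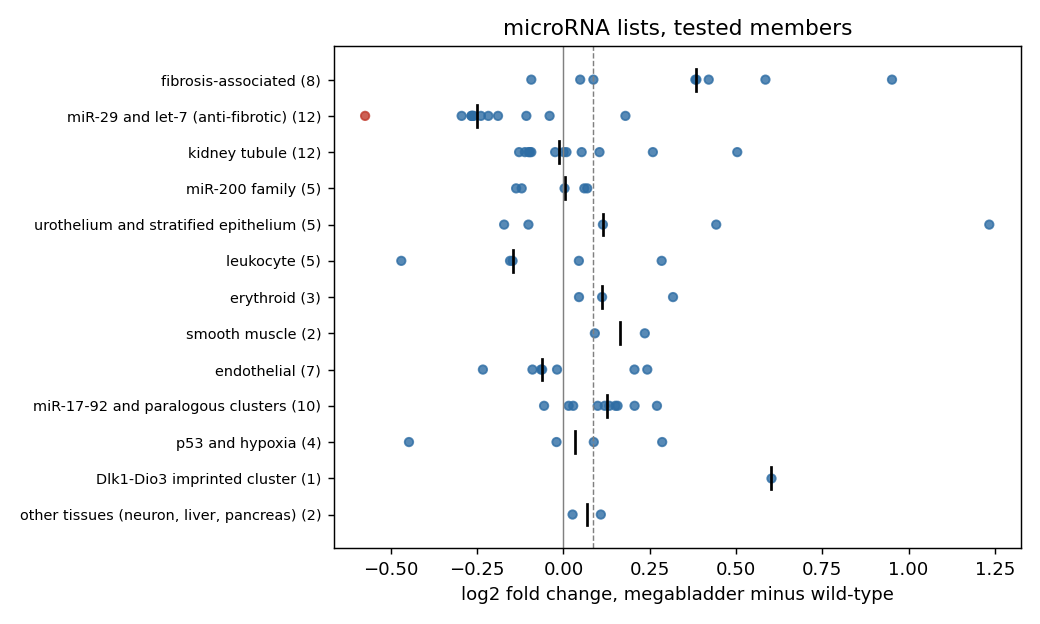
Log2 fold change (megabladder minus wild-type) of each tested member of 13 lists fixed beforehand, with the number of members in brackets. Black bars are medians, the dashed line is the median of all 213 microRNAs at 0.09, and the red point is let-7e at -0.57, the 1 member with an adjusted p under 0.05.

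The first principal component held 70.8% of the variance. It set wild-type mice 3 and 4 (7.22 and 6.92) apart from wild-type mice 1 and 2 (-1.85 and -0.99) and from the megabladder mice, whose scores (-4.10 to -3.58) lay below those of all wild-type mice. It moved with 17 microRNAs of the miR-466, miR-467, miR-669, miR-297, miR-574 and miR-1187 families, whose sequences are rich in UG or CA repeats. Their median level was 5.64 and 5.35 in wild-type mice 1 and 2, at the floor of 3.51 in wild-type mice 3 and 4, and 5.92, 5.70 and 5.83 in megabladder mice 2, 3 and 4. All 3 megabladder medians thus lay above all 4 wild-type medians, while the difference between the genotype means had a 2-sided exact permutation p of 0.171. The called miR-297a* belongs to these families, and with all 17 left out, an alternative chosen after seeing the data, 15 microRNAs passed, 6 of the 7 among them.

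**Figure D3:**
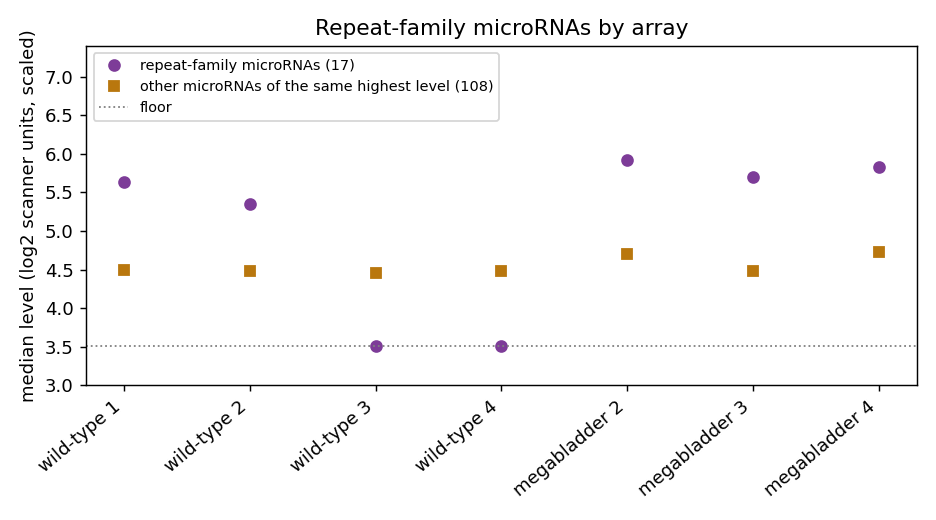
Median level of 17 repeat-family microRNAs and of 108 other microRNAs with the same range of highest levels, by array, in log2 scaled scanner units. The repeat-family median lies at the floor of 3.51 in wild-type mice 3 and 4 and between 5.35 and 5.92 on the other arrays, while that of the other microRNAs lies between 4.45 and 4.72.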

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

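All tests of explanations in this part were chosen after the results were seen. Wild-type mouse 4 had 190 microRNAs above background, apart from 204 to 206 in the other 3 wild-type mice. It was the 1 value found apart among 45 array measures and named microRNAs tested over the 4 wild-type mice, where chance gives about 1 in 20.

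Probes for mghv-miR-M1-2, a microRNA of a mouse herpesvirus that no comparison used, were above background on all 7 arrays and 0.75 log2 units higher in megabladder kidneys, with no overlap (2-sided exact permutation p = 0.0286). Unscaled, the difference was 0.16. Of the other 2 viral microRNAs above background, mcmv-miR-M23-1-5p differed by -0.05 and mcmv-miR-m88-1 by -0.04.

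In the main scaling, the count of 7 changed microRNAs was reached by 1 of 35 splits of the arrays, the real one. The highest other split, which set wild-type mice 3 and 4 and megabladder mouse 2 against the rest, gave 4. This argues against chance for the count but cannot exclude it, since 35 splits allow no share below 0.0286. The real split is also the split by slide row. The 6 risen microRNAs were all dim. Whether scaling lifted all dim signal cannot be told from the median over all 38 microRNAs of their level. That median was 0.14 with an SD of 0.43, against 0.76 for the 6, but the 6 are among the 38 and were picked by their rise. Scaling stays open as a cause: unscaled, the 6 had a median of 0.30 (0.06 to 0.52) with 0 called, and microRNAs over 100 units had -0.02 after scaling. Signal that does not come from the named microRNA also stays open, because 1 of 3 viral microRNAs was also higher, by 0.75. That one was the dimmest of the 3, at log2 levels of 3.90 in wild-type and 4.65 in megabladder arrays. let-7b*, one of the 6, had 3.68 and 4.52. The viral microRNAs that did not rise were brighter, at 6.11 and 5.20 in wild-type arrays, so they do not show how dim viral signal behaved. Genotype and slide row cannot be told apart, since 0 of 2 slide rows held both, so a biological cause remains a hypothesis.

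For the lists, chance cannot be excluded: 32 of 35 splits gave at least the 1 list past camera of the real split, and the highest other gave 5.

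The median of the repeat-family microRNAs was at the floor in wild-type mice 3 and 4. Genotype alone is argued against, since their median ranged over 2.13 log2 units within the wild-type mice. A part for genotype stays open, since the megabladder medians (5.70 to 5.92) lay above all wild-type medians (at most 5.64). Whether the Sfmbt2 gene, which carries copies of 10 of the 17, is the sole source cannot be told. The 7 with no copy there ranged over 2.34, but it was not tested whether their probes also bind RNA of the copies in Sfmbt2. A general loss of dim signal is argued against by 108 other microRNAs of the same highest levels, whose median ranged over 0.043 among wild-type mice. A loss limited to part of the dim signal stays open. Of the 108, 8 were above the floor in wild-type mice 1 and 2 and at it in mice 3 and 4, the called let-7d* and miR-1894-5p among them, and 1 was the reverse. The 75th percentile of all probes was 8.33 and 8.37 units in mice 1 and 2 and 5.74 and 4.36 in mice 3 and 4. Binding of other repeat-rich RNA to these probes was not tested and stays open, as does a difference between these mice that labels do not record.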

How the results depend on the processing

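Scaling, filter and background choices were planned, and leaving out wild-type mice 3 and 4 or the repeat families was chosen after seeing the data. Against 7 changed microRNAs, limma gave 0 with scaling by all probes (107 at an unadjusted p under 0.05), quantiles (40), normexp (35), no filter (40) and a floor of 1 (30). It gave 1 with median scaling, 69 unscaled, 2 with total gene signal, 1 with the authors' deposited values, 4 for microRNAs detected on all arrays and 17 with array weights. A change of at least 1 log2 unit left 1. Leaving out 1 array gave 0 to 11. Without wild-type mice 3 and 4 it was 1, and without the repeat families 15. The brightest probe gave 7, of which 6 were shared, and trend with robust fitting 8, of which 7 were shared.

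With mouse number as a replicate block the count was 28. No label says that the numbers pair the mice, but on every array the number equalled the slide column. The block is thus also a block by slide column across the slide rows. Deviations of same-numbered mice correlated at -0.21, 0.01 and 0.21, and of the 3 megabladder mice 1 was closest to its own number. So few values cannot exclude a pairing or an effect of slide column. Against 1 list past camera, there were 0 with scaling by all probes, quantiles, the authors' values, an estimated correlation or without wild-type mice 3 and 4. There were 2 with total gene signal or normexp and 4 with no filter. Fry gave 1, the fibrosis list in place of the miR-29 and let-7 list. Leaving out 1 array gave 1 to 2, the 2 without megabladder mouse 3. The cause of these changes was not tested.

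Where a call stood in the main or the other setting, signs turned for miR-328, to -0.070 with scaling by all probes, and for miR-429, to -0.55 unscaled. They turned for the tubule list, to a median of 3.29e-04 with no filter, and for the p53 and hypoxia list, to -0.23 without megabladder mouse 3 (-0.23 to 0.10 over all arrays left out in turn). Other list medians stayed on their side in 182 cases, lost a call in 6, gained one in 5 and changed sign uncalled in 54, in every list but that of miR-29 and let-7. Other values of named microRNAs stayed on their side in 787 cases, lost a call in 107, gained one in 31 and changed sign uncalled in 115. For part of the cases the sign was fixed in advance. Trend with robust fitting and leaving out the repeat families alter no log2 fold change of those kept. For lists, neither do an estimated correlation and fry. Low signal over background limits what the dim microRNAs can show.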

Other observations

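All tests in this part were chosen after the results were seen. Of 15 precursors with both arms tested, the passenger arm had the higher log2 fold change in 11, and the median difference over all 15 was 0.18. With scaling by quantiles it was higher in 7 and the median was -0.15. let-7b*, let-7d* and let-7f* had 0.84, 0.76 and 0.70, while their guide strands let-7b, let-7d and let-7f had -0.26, -0.04 and -0.30, and miR-21* had 0.95 against 0.09 for miR-21. The values depend on scaling: with all probes the 3 passenger arms had 0.15, 0.29 and 0.02 and the guides -1.003, -0.78 and -1.04, and with quantiles 0.38, 0.38 and 0.27 against -0.19, 0.06 and -0.23. The passenger arms were dim, with a median level of 17.3 units against 666.6 for the guides. The median difference of 0.18 is close to the gap between dim and bright microRNAs as such, whose medians were 0.14 (14.3 to 19.9 units) and -0.02 (over 100 units). 2 passenger arms and 0 guides passed in limma.

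Megabladder mouse 3 differed from the other 2 megabladder mice in several microRNAs. miR-210, induced by hypoxia, stood at 5.82 there and at 4.05 and 4.12 in mice 2 and 4. miR-192 was 9.50 against 10.35 and 10.30 and miR-194 was 7.92 against 8.66 and 8.87. miR-32, miR-362-5p and miR-532-3p were above background on all 4 wild-type arrays and on none of the 3 megabladder arrays, yet after scaling their log2 fold changes were -0.06, -0.01 and 0.12. No microRNA showed the opposite, and 17 were above background in 2 wild-type and all 3 megabladder mice.

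let-7e shares a precursor transcript region with miR-99b and miR-125a, whose genes lie within 1000 bases of its own in the GRCm38.p6 annotation. A fall of that shared transcript may lie behind the lower let-7e, and would lower all 3. In the main scaling miR-99b and miR-125a-5p had a mean log2 fold change of 0.18. Their intervals (-0.12 to 0.58 and -0.24 to 0.49) lay above let-7e's -0.57, which argues against such a fall there. Scalings by 1 factor per array move all 3 alike and so keep that gap, but not the sign of each value.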
